A study of Mus musculus with 6 samples.

How the data were processed

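The sources were the submitters' labels and 1 deposited table of FPKM values, fragments scaled by gene length and by mapped fragments, computed by the authors for 21965 genes in 6 mouse libraries, 3 labelled Aa-flox and 3 labelled Aa-cko. Per the labels' protocols, total RNA was taken with a column kit and libraries were made with a SMARTer mRNA-Seq kit. The genome build was mm10, per the submitters' processing notes; the aligner, quantifier and annotation are not given in the sources used here. The values carry 3 decimals, and 4722 genes stood at 0 in all libraries. The table pairs Ensembl gene identifiers with symbols, and 21806 identifiers were found in GENCODE mouse release M21, which gave positions on the same assembly, gene types and exon lengths. Of the genes, 21402 were protein coding and 349 were immunoglobulin or T cell receptor segments. Columns were assigned to libraries by their names, and groups come from the labels.

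Read counts were not used here. Depth was inferred from FPKM, since a gene counted in whole fragments has values in steps set by its length and the library's depth. A search from 4 to 26 M fragments gave 16.1, 16.7 and 17.4 M for Aa-flox and 14.3, 16.8 and 16.3 M for Aa-cko. At these depths 46.9 to 51.1% of held-out low values came out whole within 0.1 fragment, against 20.0% by chance. Many values were thus not whole with the exon lengths and depths used, for a reason not tested, and no count test was run. The columns summed to between 513648 and 607447 FPKM. The 20 most abundant genes held 16.2 to 19.9% of these sums and mitochondrial genes 7.18 to 9.76%. Replicates of a group correlated at Pearson 0.982 to 0.992 over log2 values, and no 2 libraries were identical.

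Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend and robust moderation of variances, over the 10849 genes with at least 1 FPKM in at least 3 libraries, with group as the only term. P-values were adjusted by Benjamini and Hochberg, and genes under an adjusted p of 0.05 are called higher or lower. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are Aa-cko minus Aa-flox. The design had provided a count test for the case that the table held counts; as it held FPKM, the test foreseen for FPKM was used. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots made with matplotlib 3.10.9.

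The test, the alternatives except the trends with GC content and length, the rule for named genes and 50 gene lists (1098 entries, of which 1096 matched the table; Mx2 and Xist are not analysed here) were fixed before the data were examined. The lists cover immune, epithelial and structural cell types of the lung, neighbouring tissues, cytokines, ferroptosis and redox genes, the LKB1 pathway, metabolism, proliferation and stress. The 44 lists with at least 5 tested members were compared with all other genes by camera with its preset correlation of 0.01, two-sided, adjusted over the lists; the Y-linked genes were a sample check without a test. By camera 15 lists were higher and 4 lower. With a correlation estimated from the 6 libraries, 0 lists passed and 9 had an unadjusted p under 0.05, and the smallest adjusted p was 0.208. That form also takes its degrees of freedom from the 6 libraries, which limits its power. Fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, passed 21 lists.

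Genes were named by rule: 8 genes fixed beforehand (Stk11, Il5, Il13, Gata3, Il1rl1, Gpx4, Slc7a11 and Acsl4); the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose mean was at least 1 FPKM, without predicted genes, clones, pseudogenes and receptor segments; up to 4 members per list with the smallest p; and the 5 genes with the largest share. Further members named because they went against their list's direction, or make up a count of 5 or fewer, were chosen after their values were seen. Errors are SDs of FPKM or standard errors of the log2 fold change, and intervals cover 95%.

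On simulated data for this comparison (10771 genes tested), the same steps recovered 74.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, and 14 of 196 calls (7.14%) were false. A list made to shift ranked 1 of 44. Only 67, 67 and 66 genes were changed 1.5-, 2- and 4-fold, against 4602 of 10849 called in the real data, so these rates may not hold there. The simulated genes varied independently, with a dispersion of 0.01. The simulation therefore does not show how the list test performs on correlated members. Alternatives covered scaling, filters, pseudocounts, the variance trend, trends with expression, GC content and length, the list test, thresholds, a block on replicate number and leaving out each library.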

Results

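RNA was sequenced from mouse samples that the labels give as lung tissue, in 2 groups of 3 libraries, labelled Aa-flox and Aa-cko. The labels do not expand Aa and do not name the gene deleted in the Aa-cko group. The series title names Lkb1, whose gene symbol is Stk11, beside group 2 innate lymphoid cells, ferroptosis and alpha tocopherol, so the comparison asks how gene expression differs between libraries with and without the deletion that the label cko stands for. Each library was available as FPKM per gene, for 21965 genes. Depth was read from the spacing of low values and came to 14.3 to 17.4 M fragments per library, so that 1 FPKM of a gene of 2 kb rested on 28.6 to 34.9 fragments. Between 10608 and 10801 genes reached 1 FPKM in a library. Nothing in the labels says that the 3 replicates of a group came from separate animals, and p-values then measure only the spread between these samples, which may be technical.

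Stk11, the gene of the kinase LKB1, was not lower in the Aa-cko libraries. It lies on chromosome 10 from 80115803 to 80130682 on the plus strand of mm10 (ENSMUSG00000003068) and was read at 57.2 ± 6.28 FPKM in Aa-flox and 59.4 ± 4.95 in Aa-cko (mean ± SD, n = 3 each). The log2 fold change was 0.05 ± 0.11 (SE), with a 95% interval from -0.196 to 0.304 and adjusted p = 0.721. Whole-gene FPKM does not show whether single exons were lost or whether a minority of cells lost the gene. Which cells the libraries hold is itself open: the labels give lung tissue and name no sort, but Sftpc, a dominant transcript of whole lung, read 3.14 FPKM in Aa-flox, and Dntt, a gene of immature lymphocytes, 92.7. The groups are therefore called the libraries labelled Aa-flox and Aa-cko, and every direction below rests on those labels. Of the 28 tested genes of the list of LKB1 partners, AMPK subunits and their substrates, 4 were higher, 7 were lower and 17 did not pass, and adjusted over the list alone the counts were also 4 and 7. Nuak2, an AMPK-related kinase that LKB1 activates, rose from 2.59 ± 0.248 to 6.67 ± 1.25 FPKM (log2 1.08 ± 0.15), Flcn, the folliculin gene, rose by log2 0.88 ± 0.17, and Prkab1, a regulatory subunit of AMPK, fell by 0.46 ± 0.09. The list as a whole did not differ from other genes (camera adjusted p = 0.882), with a median of -0.06 and a mean above 0.

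The libraries separated by group, and Il2 and Cd69 were among the largest falls. Il2, which encodes the T cell growth factor interleukin 2, stood at 32.4 ± 14.4 FPKM in Aa-flox and 0.117 ± 0.112 in Aa-cko (n = 3 each). Cd69, an early activation antigen that retains lymphocytes in tissue, fell from 878 ± 84.8 to 163 ± 7.45 FPKM, and S1pr1, the sphingosine-1-phosphate receptor by which lymphocytes leave tissue, rose from 6.09 ± 0.828 to 64.4 ± 6.42. Klf4 and Klf2, Krüppel-like transcription factors, rose by log2 3.01 ± 0.10 and 2.29 ± 0.10. With limma, 4602 of 10849 tested genes passed adjusted p = 0.05, of which 2087 (45.3%) were higher and 2515 (54.7%) lower in Aa-cko, and 257 and 302 changed at least 2-fold. The first principal component held 73.0% of the variance and parted the 2 groups, and the second held 14.3%. Under upper quartile scaling the split turned to 2708 higher (60.9%) and 1735 lower, since that scaling moved the median of all tested genes by log2 0.12, from -0.05 to 0.07, and none of the named genes past the threshold changed sign with it.

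**Figure D1:**
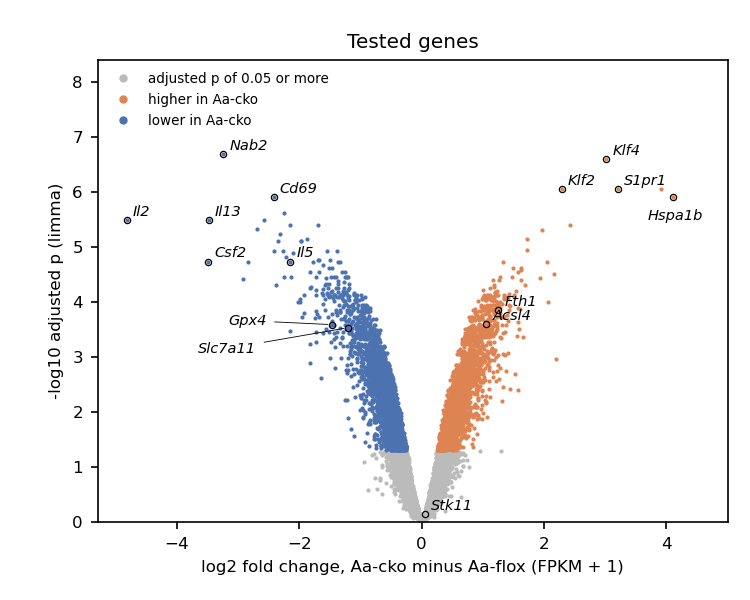
Each point is 1 of the 10849 tested genes, with the log2 fold change of Aa-cko minus Aa-flox on FPKM + 1 on the x axis and minus log10 of the limma adjusted p on the y axis. Orange points are the 2087 higher and blue points the 2515 lower genes, and Stk11 lies near the origin at 0.05.

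Among the 12 largest rises were Hspa1b (log2 4.10 ± 0.18) and Hspa1a (3.91 ± 0.16), neighbouring heat shock genes of near-identical sequence whose reads cannot be assigned with certainty. They also held S1pr1, Klf4, Klf2, Arrdc3 (2.06), an arrestin-domain protein, Alox5 (2.05), the 5-lipoxygenase gene, Rhob (1.97), a small GTPase, Slc40a1 (1.93), the iron exporter ferroportin, Lyz2 (1.68), lysozyme of macrophages and neutrophils, and Cebpa (1.62), a myeloid transcription factor. The 12 largest falls were led by Il2 (-4.82 ± 0.25), whose size is set in part by the pseudocount. They went on with Csf2 (-3.49), Il13 (-3.48), Nab2 (-3.25), a co-regulator of EGR factors, Ccl1 (-2.91), Colq (-2.85), BC035044 (-2.69), Cd40lg (-2.57), the ligand of CD40, Cd69 (-2.42), Ccr9 (-2.42), a homing receptor, Tespa1 (-2.39), a thymocyte signalling protein, and Cd5 (-2.34). The largest adjusted p among these genes was 0.000101, for Arrdc3. The genes with the largest mean share of a library were mt-Co1, Fth1, mt-Co2, mt-Co3 and Eef1a1, of which Fth1, the ferritin heavy chain, rose from 6038 ± 366 to 14385 ± 1736 FPKM. The other 4 did not pass, with log2 fold changes of -0.06 for mt-Co1, -0.16 for mt-Co2, -0.12 for mt-Co3 and 0.06 for Eef1a1.

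Cytokines of type 2 immunity were lower in the Aa-cko libraries. The fall was not confined to them, as Il2, Ifng and Xcl1, which the effector cytokine list does not hold, also fell (log2 -4.82, -1.95 and -2.26). Il13, the cytokine of mucus production, lies on chromosome 11 from 53631324 to 53634702 (minus strand, mm10) and fell from 95.4 ± 22.0 to 7.51 ± 1.20 FPKM (n = 3 each, adjusted p = 3.22e-06). Il5, the growth factor of eosinophils, lies on the same chromosome from 53720794 to 53725106 (plus strand) and fell from 73.9 ± 13.6 to 15.8 ± 2.38 FPKM (log2 -2.15 ± 0.15, adjusted p = 1.85e-05). Csf2, which encodes GM-CSF, fell from 37.7 ± 6.96 to 2.55 ± 1.28 FPKM and Lif, a cytokine of the interleukin 6 family, by 2.26 ± 0.11. Of 15 tested members of the effector cytokine list 8 fell, 1 rose (Csf1, the macrophage growth factor, log2 0.48) and 6 did not pass, with the same counts when adjusted over the list alone. The list was lower than other genes by camera (adjusted p = 0.000738, median -0.62), with adjusted p = 0.426 with an estimated correlation. In the same libraries the T cell list was lower by camera, with a median log2 fold change of -0.76, and had adjusted p = 0.208 with an estimated correlation.

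Genes that mark group 2 innate lymphoid cells moved both ways. Gata3, their lineage-defining transcription factor, fell from 36.5 ± 2.34 to 22.6 ± 5.20 FPKM (log2 -0.69 ± 0.16, adjusted p = 0.00674) and Il1rl1, the interleukin 33 receptor, from 48.1 ± 4.56 to 29.2 ± 6.12 (-0.72 ± 0.14, adjusted p = 0.00345). Gfi1, a transcriptional repressor needed by these cells, fell by 1.82 ± 0.16 and Il2ra, the interleukin 2 receptor alpha chain, by 1.52 ± 0.14, whereas Il7r, the interleukin 7 receptor, rose by 0.99 ± 0.11 and Il17rb, the receptor of interleukin 25, by 0.82 ± 0.14. Of 22 tested members 9 rose, 6 fell and 7 did not pass, or 11 and 6 adjusted over the list alone, and the list did not differ from other genes (camera adjusted p = 0.214, median 0.30). Gata3 and Il1rl1 are also expressed by T helper cells and mast cells, and RNA from mixed cells does not tell these sources apart.

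Among tested targets and effectors of type 2 cytokines in the lung, more were higher than lower. Chil3, a chitinase-like protein of macrophages, rose from 2551 ± 209 to 6325 ± 1120 FPKM, Arg1, the arginase of alternatively activated macrophages, from 403 ± 38.8 to 776 ± 64.8, and Rnase2a and Mgl2 by log2 1.39 ± 0.17 and 0.95 ± 0.13 (n = 3 each). Of the 27 genes of this list only 17 reached the filter. Of these 9 rose, 3 fell (Ccl11, Stat6 and Pdcd1lg2) and 5 did not pass, with the same counts adjusted over the list alone. By camera the list had adjusted p = 0.00621, and adjusted p = 0.42 with an estimated correlation. Chil3 also stands in the alveolar macrophage list, and the alveolar macrophage and monocyte lists rose in the same libraries with larger medians (1.07 and 1.09) than this list (0.52).

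Most T cell genes fell. Cd5, an inhibitory co-receptor of T cells, fell from 294 ± 55.0 to 56.6 ± 4.85 FPKM, Cd27, a co-stimulatory receptor, from 126 ± 24.4 to 28.0 ± 0.617, Cd6 from 137 ± 25.1 to 47.8 ± 2.42, and Trac, the constant segment of the T cell receptor alpha chain, from 421 ± 21.2 to 169 ± 10.1 (n = 3 each). Of 21 tested members 15 fell, 0 rose and 6 did not pass, with the same counts adjusted over the list alone. Camera gave adjusted p = 3.91e-07 (median -0.76), and adjusted p = 0.208 with an estimated correlation. Among genes of natural killer cells and cytotoxicity, Xcl1, the chemokine lymphotactin, fell by 2.26 ± 0.18, Ifng, the interferon gamma gene, by 1.95 ± 0.22 and Prf1, perforin, by 0.68 ± 0.11, while Nkg7 rose by log2 0.71 ± 0.12. That list held 5 higher and 4 lower genes of 21, also when adjusted over the list alone, and did not pass (camera adjusted p = 0.45), with a median of 0.13 and a mean of -0.05. Of 10 genes of type 3 innate lymphoid cells and Th17 cells, 1 rose (Il23r, log2 0.81) and 3 fell, among them Cxcr6 (-0.40) and Batf (-0.44), with the same counts adjusted over the list alone and camera adjusted p = 0.728. The calls of Cxcr6 and Batf ended under upper quartile scaling (adjusted p = 0.0886 and 0.0711).

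Regulators of lymphocyte survival and growth and of exhaustion moved in both directions. Myc, the growth-promoting transcription factor, fell from 199 ± 33.8 to 38.8 ± 3.12 FPKM and Tcf7, a T cell transcription factor, from 337 ± 16.5 to 144 ± 7.75. The survival and growth list had 5 higher and 9 lower genes of 21 (camera adjusted p = 0.342), the same adjusted over the list alone. The orphan nuclear receptors Nr4a1, Nr4a2 and Nr4a3, induced by antigen receptor signals, fell by 1.43 ± 0.19, 1.44 ± 0.17 and 1.72 ± 0.15, while Entpd1, the ectonucleotidase CD39, rose by log2 0.70 ± 0.09. The checkpoint and exhaustion list had 8 higher and 6 lower genes of 18, or 10 and 6 adjusted over the list alone. Its camera adjusted p was 0.563, and its median of 0.33 and mean of -0.12 had opposite signs. Among CREB targets regulated through CRTC coactivators, Rgs2, a regulator of G protein signalling, rose by 1.26 ± 0.10 and the Nr4a genes fell, giving 6 higher and 3 lower of 15, the same adjusted over the list alone (camera adjusted p = 0.315).

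B cell, plasma cell and myeloid genes rose. All 15 tested B cell genes were higher in Aa-cko, among them Cd22, an inhibitory receptor of B cells, Ighd, the IgD heavy chain, and Fcrla, with log2 rises of 1.35 ± 0.12, 1.42 ± 0.15 and 1.43 ± 0.15. Of 17 plasma cell genes 14 rose, 1 fell (Irf4, log2 -1.74, which activated T cells also express) and 2 did not pass, and Ighg1, an IgG heavy chain, rose from 22.4 ± 4.17 to 124 ± 8.08 FPKM. Immunoglobulin constant segments are close in sequence, so the values of Ighg1, Ighg2b and Ighg2c are uncertain where reads were shared. The camera adjusted p was 9.64e-10 for B cells and 3.81e-07 for plasma cells, and for both adjusted p = 0.236 with an estimated correlation. Adjusted over the list alone, 15 B cell genes and 15 plasma cell genes were higher.

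Macrophage and monocyte genes rose as well. Of 20 tested alveolar macrophage genes 18 rose and 2 did not pass, among them Itgax, the integrin CD11c, from 21.7 ± 1.57 to 47.1 ± 2.59 FPKM, Atp6v0d2, a proton pump subunit, by log2 1.23 ± 0.11, and Ear2, an eosinophil-associated ribonuclease, by 1.26 ± 0.13. Of 19 monocyte and interstitial macrophage genes 18 rose and 1 fell (Nr4a1), with Csf1r, the receptor of the macrophage growth factor, rising from 32.5 ± 2.68 to 80.7 ± 5.62 FPKM and Fcgr4, an Fc receptor of monocytes, by log2 1.16 ± 0.09. Dendritic cell and MHC class II genes had 14 higher, 1 lower (Irf8, log2 -0.36) and 5 not past of 20, with H2-Aa, a class II chain, rising from 507 ± 33.4 to 1077 ± 99.2 FPKM and Ciita, the class II transactivator, by log2 1.10 ± 0.12. Neutrophil genes had 12 higher, 1 lower (G0s2, log2 -0.51) and 4 not past of 17, with Csf3r, the G-CSF receptor, rising by log2 0.82 ± 0.09 and Camp, the cathelicidin, by 1.05 ± 0.13. The counts adjusted over the list alone were the same for these 4 lists. The camera adjusted p was 1.19e-10 for alveolar macrophages, 4.77e-09 for monocytes and interstitial macrophages, 2.93e-06 for dendritic cells and 0.000163 for neutrophils. In that order, they had adjusted p = 0.236, 0.208, 0.208 and 0.42 with an estimated correlation.

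Of 7 tested eosinophil genes 5 rose and 2 did not pass, or 5 adjusted over the list alone, and of these Siglecf (log2 1.07 ± 0.13), Ear1 (1.41 ± 0.22) and Ear2 also stand in the alveolar macrophage list, while Cd300lf (0.72 ± 0.10) does not. Camera gave adjusted p = 0.0023, and adjusted p = 0.42 with an estimated correlation. The eosinophil granule gene Prg2, chosen after its values were seen, did not pass (log2 0.01, adjusted p = 0.982). Mast cell and basophil genes did not pass as a list (camera adjusted p = 0.728), with 1 higher (Cma1, log2 0.79) and 2 lower (Ccl4 -0.62 and Kit -0.62) of 10. Erythroid genes had 5 higher and 2 not past of 7, with Hbb-bs, a beta globin, at 8.38 ± 2.03 FPKM in Aa-flox and 27.4 ± 6.67 in Aa-cko, and Hba-a1 and Hba-a2 are near-identical copies. That list had camera adjusted p = 0.00562, and adjusted p = 0.42 with an estimated correlation. Adjusted over the list alone, the counts of the mast cell and erythroid lists were the same.

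**Figure D2:**
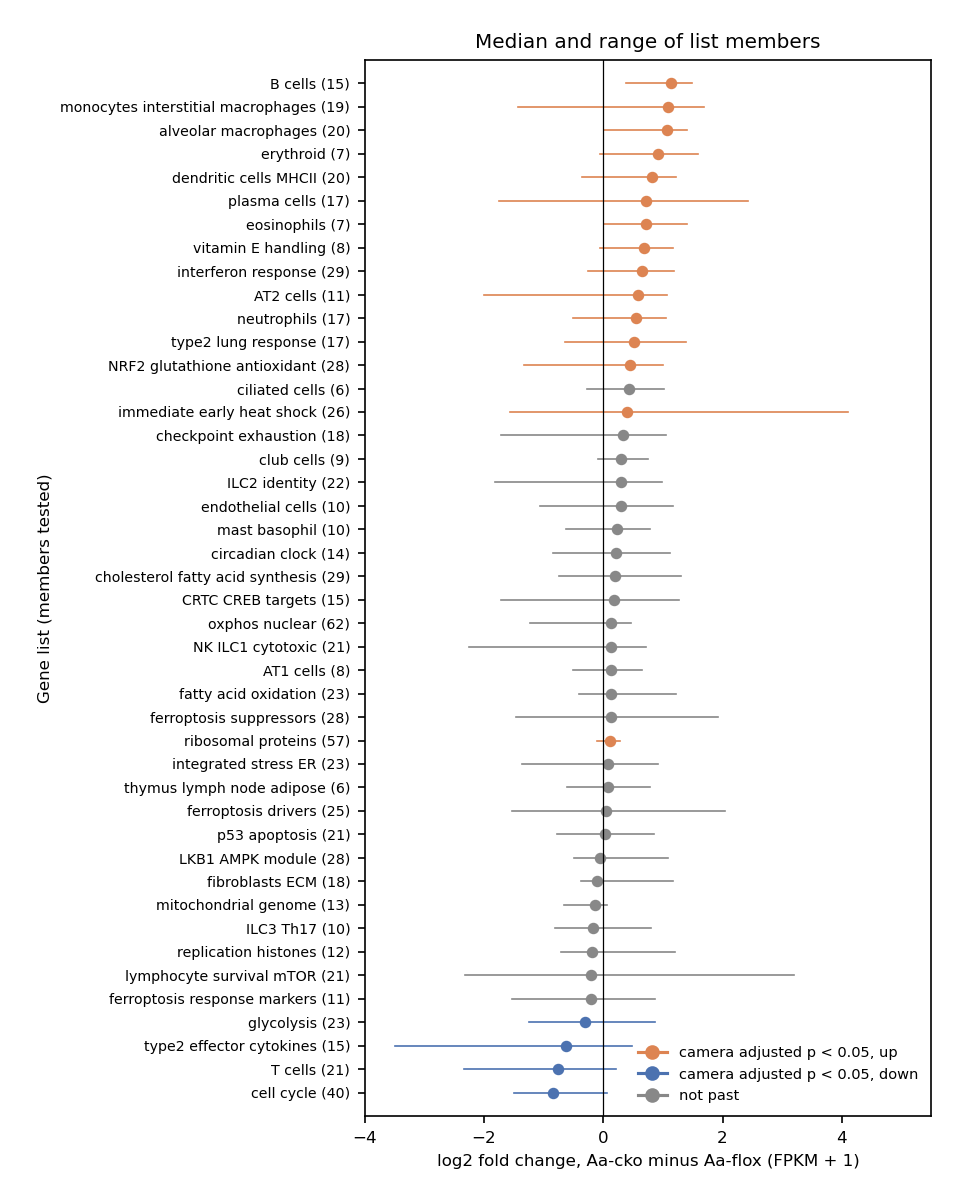
Each line spans the lowest to the highest log2 fold change (Aa-cko minus Aa-flox, FPKM + 1, x axis) of the tested members of 1 of 44 gene lists, given with the number of members tested on the y axis, and the point is the median. Orange marks the 15 lists higher and blue the 4 lists lower by camera with its preset correlation; the medians run from -0.85 for the cell cycle to 1.14 for B cells.

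Sftpc, the surfactant protein C gene, chosen after its values were seen, read 3.14 ± 1.26 FPKM in Aa-flox and 3.70 ± 1.08 in Aa-cko and did not pass (n = 3 each, log2 0.20, adjusted p = 0.523). Values this low are unusual for whole lung, and sorted or enriched cells are not excluded, so the lists below describe what these libraries held and not the lung as a whole. Of 11 tested genes of type 2 alveolar cells 7 rose, 1 fell and 3 did not pass, or 8 and 1 adjusted over the list alone. The members with the smallest p were Napsa, an aspartic protease (log2 0.95 ± 0.12), Cd74, the MHC class II invariant chain (1.07 ± 0.14), Dram1 (0.80 ± 0.12) and Etv5, an ETS transcription factor, which fell from 12.2 ± 3.74 to 2.26 ± 0.438 FPKM. Cd74 is also a dendritic cell list member. For type 2 alveolar cells camera gave adjusted p = 0.00501, and adjusted p = 0.208 with an estimated correlation. Type 1 alveolar cells (2 higher, Hopx and Cav1, and 1 lower, Rtkn2, of 8), club cells (3 higher, Cbr2, Scgb3a1 and Aldh1a1, of 9), ciliated cells (3 higher, Mlf1, Tppp3 and Ccdc153, of 6), endothelium (4 higher and 1 lower of 10) and fibroblasts and matrix (2 higher, Fn1 and Timp1, of 18) did not pass by camera, with adjusted p = 0.462, 0.0597, 0.165, 0.171 and 0.717. Club cells passed upward in other settings, with adjusted p = 0.043 scaled without the 20 most abundant genes, 0.0117 with no filter, and 0.0189 and 0.0143 without Aa-cko replicates 1 and 3. Fibroblast genes had a median of -0.11 and a mean of 0.04. In the endothelial list Car4, Ednrb, Vwf and Epas1 rose and Calcrl fell, and Car4 is shared with alveolar macrophages. For these 5 lists the counts adjusted over the list alone were the same. Too few genes of goblet cells (4 tested, 3 higher, Ltf, Reg3g and Tff1), mesothelium (2 tested, both higher, Msln and Krt19), smooth muscle and pericytes (3 tested, 0 past), heart muscle (1 tested, 0 past) and skeletal muscle (1 tested, 0 past) reached the filter for a list test, and adjusted over the list alone 4 goblet cell and 2 mesothelial genes were higher. The calls of Rtkn2, Cbr2, Scgb3a1, Aldh1a1, Ccdc153, Ednrb, Vwf, Timp1, Tff1 and Msln ended in at least 1 alternative setting.

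Regulators of ferroptosis, the iron-dependent cell death by lipid peroxidation, moved both ways. Gpx4, the glutathione peroxidase that reduces lipid peroxides, lies on chromosome 10 from 80047166 to 80056439 (plus strand, mm10; ENSMUSG00000075706) and fell from 237 ± 43.5 to 85.7 ± 20.2 FPKM (n = 3 each, log2 -1.47 ± 0.18, adjusted p = 0.000258). Slc7a11, the cystine transporter that feeds glutathione synthesis, fell from 185 ± 8.71 to 81.1 ± 18.6 (log2 -1.21 ± 0.15, adjusted p = 0.000293), and Gss, glutathione synthetase, by 1.33 ± 0.12. In contrast, Acsl4, which builds polyunsaturated fatty acids into lipids, rose from 33.8 ± 3.45 to 71.4 ± 9.99 FPKM (log2 1.05 ± 0.13, adjusted p = 0.000254), and Fth1, Slc40a1 and Nfe2l2, the gene of NRF2, rose by 1.25 ± 0.13, 1.93 ± 0.15 and 0.88 ± 0.10. Tfrc, the transferrin receptor, fell by 1.54 ± 0.13 and Trp53, the p53 gene, by 1.33 ± 0.09. The suppressor list had 9 higher and 8 lower of 28 genes, or 10 and 8 adjusted over the list alone, and the driver list 9 higher and 5 lower of 25, or 10 and 5 adjusted over the list alone. Neither differed from other genes (camera adjusted p = 0.545 and 0.459). In the same libraries the T cell and cell cycle lists fell (medians -0.76 and -0.85). The alveolar macrophage and monocyte lists rose (1.07 and 1.09). Whether the changes of ferroptosis genes came from the mix of cells or from expression within cells was not tested. Genes induced during ferroptosis had 3 higher (Ddit3, Atf3 and Hmox1) and 5 lower of 11, the same adjusted over the list alone, with Ptgs2, cyclooxygenase 2, falling from 414 ± 43.8 to 186 ± 17.5 FPKM and Trib3 by 1.03 ± 0.13. That list passed fry, which tests whether its members moved one way on balance (adjusted p = 0.00557, downward), and not camera (adjusted p = 0.361).

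NRF2 targets and genes of glutathione metabolism were mostly higher. Osgin1, an oxidative stress gene, rose from 55.2 ± 5.69 to 112 ± 5.83 FPKM, Srxn1, sulfiredoxin, from 79.2 ± 4.42 to 138 ± 4.81, and Mgst1, a microsomal glutathione transferase, from 29.2 ± 0.960 to 51.9 ± 3.14 (n = 3 each). Of 28 tested members 17 rose, 2 fell (Slc7a11 and Gss) and 9 did not pass, with the same counts adjusted over the list alone. The camera adjusted p was 6.81e-05 (median 0.45), and adjusted p = 0.426 with an estimated correlation. The alveolar macrophage, monocyte and neutrophil lists rose in the same libraries with larger medians (1.07, 1.09 and 0.56), and the T cell list fell (-0.76). Of 8 tested genes of vitamin E uptake and transport 5 rose and 3 did not pass, the same adjusted over the list alone. Among them were Pltp, phospholipid transfer protein (log2 1.16 ± 0.15), Lpl, lipoprotein lipase (1.08 ± 0.13), Cd36, a scavenger receptor (0.96 ± 0.12), and Abca1, a cholesterol exporter (0.55), which handle lipids in general. Lpl, and Abcg1, 1 of the 3 that did not pass, also stand in the alveolar macrophage list, whose median rose by 1.07 in the same libraries. For vitamin E handling camera gave adjusted p = 0.00512, and adjusted p = 0.208 with an estimated correlation. Ttpa, the tocopherol transfer protein, stayed below the filter.

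Proliferation genes were lower. Cdk1, the mitotic kinase, fell from 43.7 ± 3.74 to 14.8 ± 0.255 FPKM, Ccnb1, cyclin B1, from 18.7 ± 0.672 to 7.27 ± 0.583, and Rrm2, a ribonucleotide reductase subunit, from 53.4 ± 7.12 to 21.9 ± 0.528 (n = 3 each). In the same libraries the T cell list fell (median -0.76) and the B cell and alveolar macrophage lists rose (medians 1.14 and 1.07). Of 40 cell cycle genes 39 fell and 1 did not pass (Cenpa, log2 0.06), the same adjusted over the list alone. This list had the smallest camera adjusted p of the 44, 3.72e-14 (median -0.85), and adjusted p = 0.208 with an estimated correlation. Replication-dependent histone genes, whose transcripts lack poly(A) tails, had 3 higher (H1f2, H2bc4 and H2ac18) and 3 lower (H4c3, H1f5 and H3c13) of 12, the same adjusted over the list alone, with camera adjusted p = 0.728, a median of -0.19 and a mean of 0.06.

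The glycolysis list was lower. The glucose transporters Slc2a1 and Slc2a3 fell from 124 ± 16.2 to 56.1 ± 4.56 and from 40.9 ± 2.18 to 16.8 ± 2.81 FPKM, Pfkl, a phosphofructokinase, by 1.06 ± 0.13 and Hk1, hexokinase 1, by 0.75 ± 0.11. Of 23 glycolysis genes 9 fell, 2 rose (Hk3 and Aldoc) and 12 did not pass, or 10 and 2 adjusted over the list alone. In the same libraries the T cell and cell cycle lists fell (medians -0.76 and -0.85) and the alveolar macrophage and B cell lists rose (1.07 and 1.14). Glycolysis had camera adjusted p = 0.00562 (median -0.31), and adjusted p = 0.553 with an estimated correlation. In the integrated stress and endoplasmic reticulum list, Mthfd2, Shmt2, Phgdh and Psat1, enzymes of serine and one-carbon metabolism that ATF4 controls, fell by 1.36 ± 0.10, 1.29 ± 0.12, 1.20 ± 0.12 and 1.05 ± 0.11. That list had 8 higher and 9 lower of 23, the same adjusted over the list alone, with camera adjusted p = 0.607, a median of 0.08 and a mean of -0.21, and passed fry downward (adjusted p = 0.0138).

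Of 62 nuclear genes of oxidative phosphorylation 2 fell, Cox5a from 312 ± 89.3 to 131 ± 24.6 FPKM and Uqcrc2 by 0.31 ± 0.10, and 60 did not pass (camera adjusted p = 0.112). The call of Uqcrc2 ended in some settings. The list passed upward by camera under upper quartile scaling (adjusted p = 0.0445) and without Aa-cko replicate 3 (0.000432). The mitochondrial genome had 1 lower gene, mt-Atp8 (log2 -0.67 ± 0.17), of 13 (camera adjusted p = 0.422, median -0.15). It passed downward under quantile normalization (adjusted p = 0.00157, median -0.356) and with the expression trend (0.0229, -0.381) or the length trend (0.00451, -0.458) taken out. Adjusted over the list alone, 1 nuclear and 1 mitochondrial gene passed. Fatty acid oxidation had 5 higher and 3 lower (Hadhb, Etfdh and Ppard) of 23 (camera adjusted p = 0.143), with Eci1, an enoyl-CoA isomerase, rising by log2 1.21 ± 0.19, and cholesterol and fatty acid synthesis 8 higher and 4 lower of 29 (camera adjusted p = 0.205), with Scd1, the stearoyl-CoA desaturase, rising by 1.31 ± 0.16. Adjusted over the list alone, the counts of these 2 lists were the same. The call of Hadhb ended in some settings. The fatty acid oxidation list passed fry upward (adjusted p = 0.0221). The 57 ribosomal protein genes had 0 past the threshold by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, with a median of 0.12. The list had camera adjusted p = 0.0464, and adjusted p = 0.831 with an estimated correlation, and its median turned below 0 under quantile normalization and when a trend with mean expression or length was taken out, and also without Aa-cko replicate 2. With a median above 0 the call also ended when scaled without the 20 most abundant genes (adjusted p = 0.054), with no filter (0.0711), with the GC trend taken out (0.171), without Aa-flox replicate 3 (0.311) and by fry (0.624).

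Interferon-stimulated genes rose. Ifit1, an antiviral RNA-binding protein, rose from 38.1 ± 4.53 to 87.4 ± 7.39 FPKM, Oasl1 from 166 ± 22.2 to 361 ± 19.9, Cxcl10, a chemokine for activated T cells, from 122 ± 14.4 to 256 ± 11.5, and Mx1 by log2 1.13 ± 0.12 (n = 3 each). Of 29 tested members 23 rose, 0 fell and 6 did not pass, or 24 and 1 adjusted over the list alone. The monocyte, dendritic cell and B cell lists rose in the same libraries (medians 1.09, 0.82 and 1.14) and the T cell list fell (-0.76). As a list the interferon genes had camera adjusted p = 6.79e-10 (median 0.66), and adjusted p = 0.208 with an estimated correlation. The list of immediate early and heat shock genes, which respond to tissue dissociation and handling as well as to signals, had 15 higher, 6 lower and 5 not past of 26, or 16 and 6 adjusted over the list alone, led by Hspa1b, Hspa1a, Klf4 and Klf2. Camera gave this list adjusted p = 0.000593, and adjusted p = 0.45 with an estimated correlation. Genes of p53 and apoptosis had 7 higher and 5 lower of 21, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.521), with Pmaip1, the gene of the cell death factor NOXA, rising by log2 0.86 ± 0.16. Circadian clock genes had 5 higher and 1 lower (Bmal1, log2 -0.85) of 14, the same adjusted over the list alone (camera adjusted p = 0.0717), with Nfil3 rising by log2 1.12 ± 0.11. The clock list passed upward with the length trend taken out (adjusted p = 0.0325) and without Aa-flox replicate 3 (0.0448) or Aa-cko replicate 2 (0.0216).

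Of 6 tested genes of thymus, lymph node and fat, which lie next to the lung, 1 rose (Cidec, a lipid droplet protein that the alveolar macrophage list also holds) and 2 fell, and adjusted over the list alone 1 and 2. Dntt, the terminal transferase of immature lymphocytes, fell from 92.7 ± 1.21 to 60.3 ± 2.75 FPKM and Rag2, a recombinase subunit, by 0.60 ± 0.14, while Rag1 read 6.11 ± 2.40 and 7.96 ± 2.89. By camera this list had adjusted p = 0.882, downward, while its median was 0.08. These genes were present in both groups, beside the fall of the T cell list. The 4 tested genes of the Y chromosome were lower in Aa-cko, with Eif2s3y at 18.0 ± 2.45 and 8.59 ± 0.491, Ddx3y at 14.9 ± 3.97 and 5.32 ± 1.45, Uty at 2.99 ± 0.806 and 0.836 ± 0.0340, and Kdm5d at 1.91 ± 0.464 and 0.524 ± 0.0782 FPKM in Aa-flox and Aa-cko, and all 6 libraries held them.

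**Figure D3:**
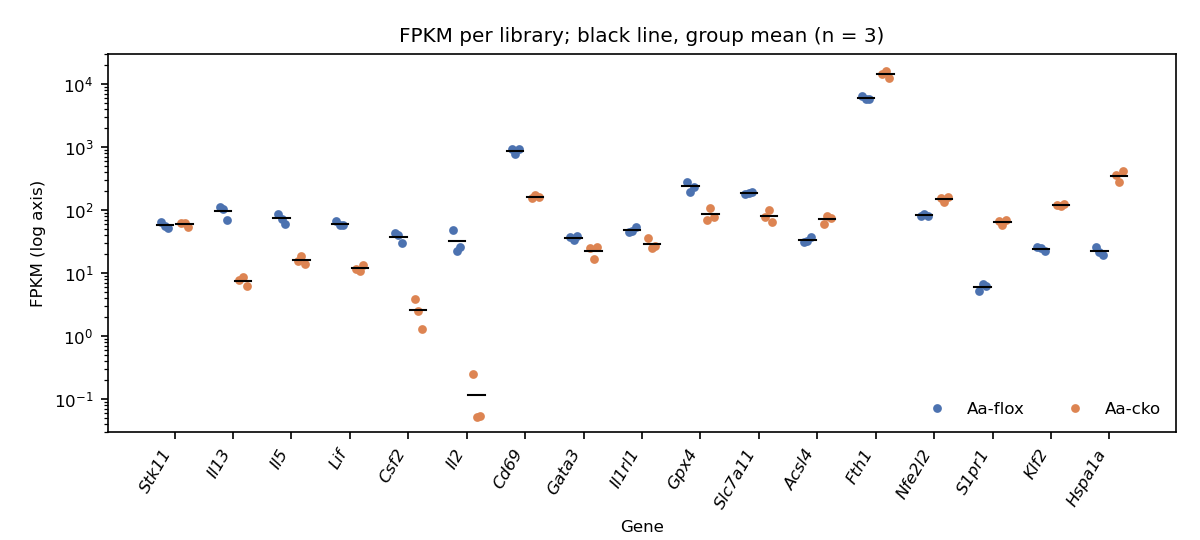
Points are the FPKM of each library (log y axis, 3 per group) for 17 genes on the x axis, and black lines are group means. Stk11 overlaps between Aa-flox (blue) and Aa-cko (orange), Il13, Il5, Gpx4 and Slc7a11 lie lower in every Aa-cko library, and Acsl4, Fth1 and S1pr1 lie higher.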

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

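The alternatives that took out a trend with GC content or with gene length were added after the results were seen; the others were planned. Without single libraries the counts of 2087 and 2515 ranged from 1443 to 2022 higher and from 1795 to 2734 lower. At an adjusted p of 0.01, 1269 genes were higher and 1479 lower, and with at least 2-fold change 257 and 302, since these thresholds are stricter. Upper quartile scaling gave 2708 higher and 1735 lower. Lists counted 15 higher and 4 lower, and 0 and 0 with an estimated correlation. A higher correlation was not the only cause of this loss. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries, and with the preset one from the number of genes. Its p-values therefore rise even where the correlation does not. How much each added for a given list was not tested. Type 2 alveolar cells and vitamin E handling had estimated correlations of -0.0533 and -0.0263, below the preset 0.01, and were lost too. Leaving out single libraries gave 15 to 17 higher and 4 lower. Of 177 named genes past the threshold, 15 lost the call under some alternative, and 0 changed sign. Under some alternative 7 further lists passed, 3 of them by fry alone. Stk11 did not pass in any setting and changed sign with the GC trend taken out (-0.0579) and without Aa-flox replicate 3, ranging from -0.0136 to 0.137 without single libraries; the cause was not tested. The ribosomal protein median turned to -0.0316 under quantile normalization, -0.0843 with the expression trend and -0.0475 with the length trend taken out; the cause was not tested.

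Replicate numbers are shared between the groups, but nothing says that they pair samples. After each gene's group mean was subtracted, the deviations of same-numbered libraries correlated at -0.0179, 0.188 and 0.522. Those of Aa-flox 1 correlated best with those of Aa-cko 2 (0.365). With a replicate block, 2451 genes were higher and 3058 lower, Stk11 remained at 0.05, and the club cell and nuclear oxidative phosphorylation lists passed upward (adjusted p = 0.0352 and 0.0366). The FPKM unit left the planned count tests and their size factors not run. Depth limits genes near 1 FPKM most.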

Other observations

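All tests in this part were chosen after the results were seen, apart from the count over splits of the libraries, and the tests of cytokines, thymocyte genes and Y-linked genes were also given other forms after their first results were seen.

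Heat shock and immediate early genes were tested as 1 list. Of its 8 heat shock genes 7 rose and 0 fell (median log2 0.55), and of 15 immediate early genes 5 rose and 6 fell (median 0.09). Klf2, Klf4 and Klf6, set in neither part, all rose, and the difference between the parts was not tested. Among immunoglobulin variable segments 74 of 128 rose and 0 fell. Their median SD between replicates was 0.336 on the log2 scale, against 0.175 for genes matched on mean expression. The X-linked partners of the Y-linked genes did not all hold level: Ddx3x fell from 186 ± 11.8 to 118 ± 17.4 FPKM (adjusted p = 0.00215), while Kdm5c, Kdm6a and Eif2s3x did not pass (log2 0.17, 0.25 and -0.15). Gpx4 and Stk11 are neighbours on chromosome 10, and Gpx4 fell while Stk11 did not pass. Groups did not overlap in 53.3% of tested genes, against 10% by chance, and 5515 genes had an unadjusted p under 0.05. Of the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05, 1 gave at least 4602 genes, the real one, and the highest other count was 0.

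The type 2 effector cytokine list, of which 8 members fell, could reflect a lower share of T-lineage cells, or a few abundant transcripts that take more of each library. Against the second, scaling without the 20 most abundant genes moved the median of all tested members by 8.68%, from -0.62 to -0.67. On the first, 7 of 15 tested members had a 95% interval wholly below the T cell list mean of -0.82. Among them were Il13 and Il5. By the bound written for this test, the count of 7 would have counted against a lower share as the whole cause. The count does not decide, as Cd5 and Cd27, members of the T cell list, also lay wholly below that mean. The interval of Il13 (-3.88 to -3.09) lay below that of Cd5 (-2.66 to -2.03), the largest fall in the T cell list. That of Il5 (-2.48 to -1.81) overlapped the interval of Cd5. Earlier forms gave -0.36 (-1.03 to 0.31) for the median of all members less that of the whole T cell list, which decides nothing as members went both ways, and -1.36, -1.15 and 2.36% on the 8 that fell, which were picked for falling. A lower share of T-lineage cells, lower expression per cell, and fewer cells of a cytokine-producing subset stay open as hypotheses. As Stk11 was not lower, a link to the deletion was not tested.

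The fall of the T cell list could come from a lower share of T-lineage cells or from unequal amounts of thymus RNA. With the first as the whole cause the members would fall by about the same amount only if T-lineage cells were their sole source. In 12 of 21 the 95% interval excluded the list mean of -0.82. This count passed the bound written for the test, which would have counted against this explanation. Members that other cells also express may fall less, so the count alone does not decide. Of 7 tested thymocyte genes 5 fell, from 92.7 to 60.3 FPKM for Dntt and at most by log2 1.02, for Mns1, and Rag1 and Aqp11 did not pass. Only 2 of 21 T cell genes, Cd5 and Cd27, had an interval wholly below that of Mns1, whose lower bound was -1.46, while 5 lay below its point value, the form first run, which by its own bound of 3 would have excluded this explanation. Neither a lower share of T-lineage cells nor unequal thymus RNA is therefore decided, and a change of expression within T cells was not tested.

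The Y-linked genes may have fallen through a different mix of male and female cells, if libraries were pooled, or through a lower share of T-lineage cells. The mean log2 ratio of Uty, Kdm5d and Ddx3y to Eif2s3y, which a mix alone would leave level, differed by -0.66, with a 95% interval from -1.37 to 0.05 that holds 0. Without Ddx3y, the form first run, it differed by -0.77 (-1.42 to -0.12), which excludes 0, so this explanation is not decided. Their per-library median less that of the whole T cell list differed by -0.57 (log2 FPKM, 95% interval -1.42 to 0.28), by -0.15 in an earlier form on log2(FPKM + 1), and by -0.24 against only the T cell genes that fell, which were picked for falling. Both stay open, and the labels used here do not give the sex of the animals.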
